A study of Drosophila melanogaster with 2 samples.

How the data were processed

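Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos, 0 to 24 h old and of mixed sex, per the labels. The flies carried an eGFP exon placed in an intron of a gene, so that the gene's protein was made with GFP attached, and chromatin was precipitated with an antibody against GFP. Chromatin was sheared by sonication to 200 to 800 bp. The labels give 2 biological replicates of 1 group and no second condition, so no comparison between groups was made. The labels name the tagged gene in 2 ways: the strain and fusion are called Side, and the insertion is said to target Sidpn. In the annotation used here side (sidestep) and Sidpn (similar to deadpan) are different genes, and both are reported; which of them was tagged is not settled by the sources used here. The antibody field of the labels says Side, while the description says that the antibody was against GFP.

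The authors deposited narrow peak lists on the dm6 and dm3 builds. Per the deposited file records, a candidate list of peaks and background was made for each replicate and for both replicates pooled. Each list was made against the same single control, as input for the irreproducible discovery rate (IDR) procedure. That procedure compares the ranks of peaks between replicates. A further deposited list holds the optimal set of peaks past the IDR threshold; its peaks are called thresholded peaks below. The peak caller, its version, the IDR threshold and the aligner are not given in the sources used here. Column 7 of the deposited lists holds the signal of each peak, a value of the authors' caller whose scale is not stated. It was used to rank and describe peaks, to compare the replicates, and to test promoter against other thresholded peaks. Column 9 of the deposited lists holds the −log10 of the q-value by the definition of the format, and it was not used for any test because it takes the single value 4.08 in every thresholded peak on dm6. Read totals are not given in the sources used here, so the depth of each replicate is unknown and no interval that needs it was computed. Alignments and signal tracks named in the file records were not analysed here.

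Sequence was taken from Release 6 of the genome, and genes and start sites were taken from Ensembl release 115 (annotation version 6.54), leaving out transposable elements and pseudogenes. Coordinates are 1-based on dm6. Lists on dm3 entered only counts, widths, signals, replicate overlaps and correlations, and chromosome arms, and no coordinate was converted. Thresholded peaks were compared with the 24883 candidates of the pooled list that overlapped none of them, the regions that could have passed the threshold. A summit within 500 bp of an annotated start site was called a promoter summit; other summits were classed as 5' UTR, coding exon, 3' UTR, exon of a noncoding RNA, intron or intergenic, in that order. The class for exons of noncoding RNAs was added after the files were opened, because such summits fit none of the other classes. Classes, genes of small RNAs, chromosome arms, gene lists and motifs were tested with 2-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Odds ratios are given with 95% intervals, and shares with 95% Wilson intervals; both cover counting error only, and neighbouring peaks or genes that share a promoter peak are not independent.

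Gene lists were tested among the protein-coding genes with a candidate summit within 500 bp of a start site, asking how many had a thresholded summit there. The 23 lists and 21 motifs, the tests, the alternatives and the rule for naming genes were fixed before the data were examined; older gene symbols were then matched to current ones. Motifs were searched on both strands within 100 bp of the summit. Replicate overlap was the share of the 4097 highest-signal peaks of replicate 1 that overlapped 1 of the 4097 highest of replicate 2 by at least 1 bp, tested one-sided against 1000 circular shifts within chromosomes. Signals of replicates were correlated over each peak of replicate 1 and its highest-signal overlapping peak of replicate 2, with an interval from 1000 bootstraps. The signal of promoter and other thresholded peaks was compared with a 2-sided permutation test of 100000 resamples. Genes were named by rule: the nearest gene within 500 bp for each of the 25 thresholded peaks of highest signal, side and Sidpn, all members of the HES family, and in each list up to 4 members with the highest promoter signal, or the first 2 with a candidate where no member had a thresholded peak. Genes named outside this rule were all chosen after their values were seen. They are cbt, CG44290, the neighbours of Sidpn, the genes of small nuclear RNAs and the partner of mbc at a shared peak. Also among them are ribosomal protein genes without a thresholded peak and genes of lists added later.

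Alternatives were promoter windows of 200 and 1000 bp, the 1000 thresholded peaks of highest signal, each replicate left out (the same number of top peaks of the other replicate in place of the thresholded set), other overlap rules, dm3 in place of dm6, other background genes, assignment of each peak to the nearest gene within 5 kb, a motif window of 50 bp, and candidates matched on GC content in bins of 2 percentage points, alone or together with promoter status. The tests were checked on simulated data. In 100 simulations of 23 lists of 25 genes among 8000 genes, a list with planted promoter peaks was recovered in 97% of runs. Of the other lists 0.545% passed. The planted excess was large and all 25 genes had a candidate, so the 97% gives no power for smaller lists or weaker differences. In 20 simulations of motifs in 5000 sequences, the planted motif was recovered in 100% of runs and 0.263% of the other motifs passed. Both simulated sets had the same base composition, while thresholded peaks and other candidates differed in GC content. The 0.263% therefore gives no rate of false calls for the motif test without matching. In 50 simulations of annotation classes, planted differences were recovered in 100% of runs, and 4% of the other classes passed. The signal test passed in 50 of 50 simulations with a planted difference and in 3 of 50 without any. That planted difference was larger than the one observed in the data. Independent peak lists passed the overlap test in 0 of 20 simulations, and lists with planted sharing in 20 of 20. Versions were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.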

Results

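Binding of a GFP-tagged protein, called Side-eGFP in the labels, was mapped in whole fly embryos from 2 biological replicates. Each replicate and the pool of both was represented by a list of 30000 candidate peaks on dm6, and a further list held 4097 peaks past the authors' IDR threshold. Depth is unknown for both replicates. Coordinates are 1-based on dm6, and signal has the unit of the authors' peak caller.

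The thresholded peaks formed 3959 separate regions covering 1.41 Mb of the genome. They were the 4097 candidates of highest signal in the pooled list, 13.7% of it, and the lowest had a signal of 81.5. The list was thus the top of the pooled ranking, and a single thresholded peak need not rank alike in both replicates. Their median signal was 124 and the highest 2300, against a median of 32.2 over all pooled candidates. On dm3 the list held 4222 peaks with a median signal of 121, and the highest signal was again 2300. Median peak width was 410 bp on both builds.

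The strongest peak lay on chromosome 2L (480876 to 481323), inside an intron of ush and 1365 bp upstream of cbt (FBgn0043364), which encodes the zinc finger factor cabut and was named after its peak was seen, and ranked first in both replicates. Of the 25 strongest peaks, 17 had a summit within 500 bp of a start site. The strongest of these were at Ugalt (FBgn0024994, X, 2703684 to 2704092), a UDP-galactose transporter gene, with a signal of 1912 and its summit 39 bp upstream of the start site, and at CG14100 (FBgn0036889, 3L, 19590436 to 19590809), with 1779. The promoter of ph-p (X, 2137090 to 2137575), a Polycomb group gene, held a peak of signal 1505, and those of CG1888 and Chro, a gene for a chromatin protein of interbands, held peaks of 1395 and 1234. Promoter peaks at PNPase (1184), larp (1115), Art3 (1110), CenG1A (1059), mRpL41 (1034), Sox14 (969), CG9147 (968), CG31145 (939), Pal1 (939) and Tcs5 (917) followed, with the remaining promoter summits at the noncoding RNA genes CR31840 and CR44619. Each of the 25 peaks ranked 31 or better in both replicates.

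The replicates ranked many of the same regions at the top. Of the 4097 highest-signal peaks of replicate 1, 73.0% overlapped a top peak of replicate 2, against a mean of 2.29% and a highest value of 3.27% over 1000 circular shifts (permutation test, one-sided, p = 0.001, the smallest these shifts can give). Of the thresholded peaks, 87.7% were among the top 4097 of replicate 1, 83.7% among those of replicate 2, 72.4% in both, and 43 peaks in neither. Across 18662 overlapping pairs of peaks, signals correlated with a Spearman rho of 0.61 (95% bootstrap interval 0.60 to 0.62) and a Pearson r of 0.72 on the log2 scale. Peaks are not independent replicates, so no p is given. The bootstrap resampled pairs as if they were independent, so its interval does not measure the uncertainty of replicate agreement. The log2 ratio of the replicates' signals had an SD of 0.73. With mutual best pairs, a pairing chosen after the first value was seen, rho was 0.70 over 15712 pairs. Both replicates were called against the same control, and its part in the overlap was not separated. The shifts did not keep the concentration of peaks at promoters, so passing shows only more overlap than random placement. It does not show that the shared regions are sites of the tagged protein.

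Thresholded peaks lay at promoters more often than the other candidates did. Promoter summits made up 56.4% of thresholded peaks (2311 of 4097, 95% interval 54.9 to 57.9) and 30.5% of the other candidates, an odds ratio of 2.95 (2.75 to 3.15, Fisher's exact test, adjusted p = 1.7e-217). Coding exons held 13 thresholded summits (0.317%), against 11.9% of the other candidates, an odds ratio of 0.0235 (0.0125 to 0.0404, adjusted exact p = 5.1e-183). Introns held 30.4% against 37.7% (odds ratio 0.722), intergenic sequence 10.7% against 15.3% (0.662), 3' UTRs 0.805% against 2.22% (0.357) and 5' UTRs 0.635% against 1.29% (0.487), each with an adjusted p of 1.6e-04 or below. Exons of noncoding RNAs did not pass (odds ratio 0.711, 0.473 to 1.04, adjusted exact p = 0.077), but passed without replicate 1 (0.552, adjusted exact p = 0.0033). The call for 5' UTRs was lost in the 1000 strongest peaks (0.538, adjusted exact p = 0.13). The odds ratio of coding exons was 0.0373 without replicate 1, that of 3' UTRs 0.220 without replicate 1 and 0.177 in the 1000 strongest peaks, and that of 5' UTRs 0.226 with a promoter window of 1000 bp, all still past the threshold. Candidate lists hold peaks and background, so these odds ratios compare strong with weak regions of the same immunoprecipitation.

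**Figure D1:**
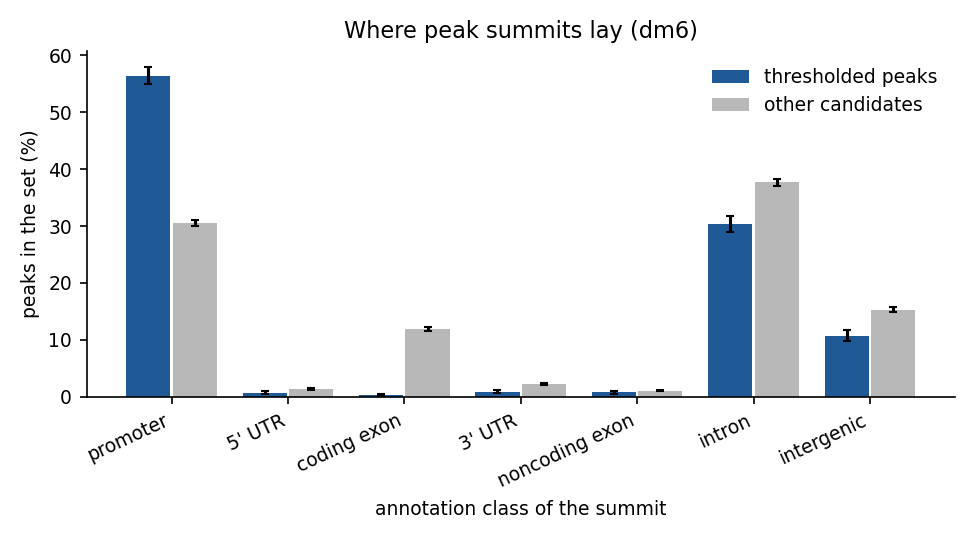
Share of peak summits in each annotation class on dm6 (y axis, % of the set), for the 4097 thresholded peaks and the 24883 other candidates of the pooled list; bars show shares and error bars 95% Wilson intervals. Promoter summits made up 56.4% of thresholded peaks and 30.5% of the other candidates, and coding exons 0.317% and 11.9%.

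The median thresholded summit lay 292 bp from the nearest start site, and the median summit of the other candidates 1262 bp. Among promoter summits, thresholded ones were centred upstream, with a median position of -59 bp (quartiles -149 and 7.5 bp), while those of the other candidates had a median of 2 bp. Within 100 bp of a start site lay 30.6% of thresholded summits and 13.1% of the others.

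**Figure D2:**
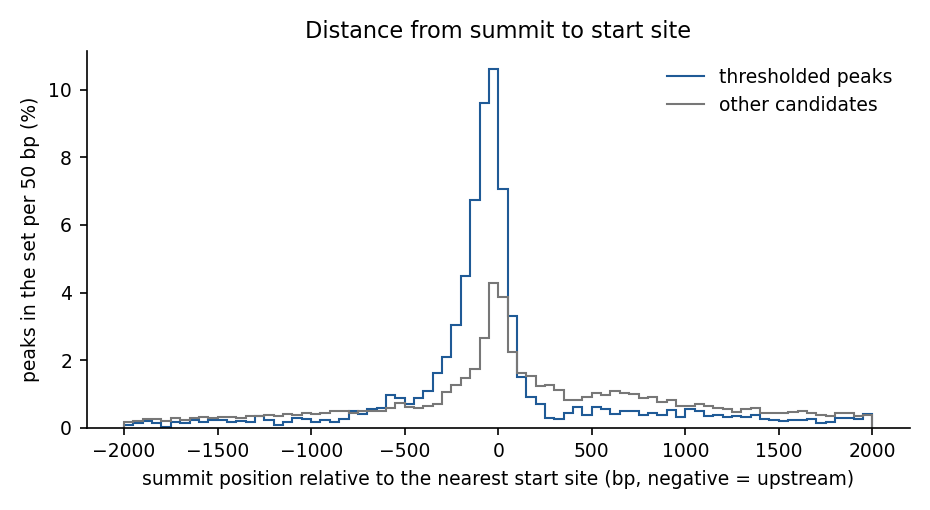
Position of summits relative to the nearest annotated start site (x axis, bp, negative values upstream) as the share of each set per 50 bp (y axis, %). Lines show thresholded peaks and other candidates; thresholded promoter summits had a median of -59 bp.

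Promoter and other thresholded peaks differed little in signal. Mean log2 signal was 7.18 ± 0.75 (SD, n = 2311 peaks) at promoters and 7.14 ± 0.69 (SD, n = 1786 peaks) elsewhere, a difference of 0.048 (2-sided permutation test, p = 0.034). The direction turned with a promoter window of 200 bp (difference -0.039, permutation p = 0.085), and without replicate 2 the difference was 0.036 (permutation p = 0.12), so it did not hold against these settings. It was larger with a window of 1000 bp (0.083, permutation p = 4.7e-04) and without replicate 1 (0.059, permutation p = 0.0081).

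Genes of cytosolic ribosomal proteins stood apart from the other gene lists. Of the 81 with a candidate promoter peak, 68 (84.0%, 95% interval 74.5 to 90.4) had a thresholded one, against 2734 of all 7757 genes with a candidate (35.2%), an odds ratio of 9.83 (5.37 to 19.4, Fisher's exact test, adjusted p = 3.5e-18). The highest signals were at RpS27 (722, ranked 49 in the pooled list and 52 and 49 in the replicates), RpL7 (603), RpL23A (569) and RpL14 (526), and the median over the 68 genes was 225. The odds ratio was 7.96 without replicate 1 and 9.63 without replicate 2. Named after their values were seen, the 13 genes with a candidate and no thresholded peak included RpS30 (signal 80.7, just under the threshold), RpL12 (74.8), RpS3 (64.7) and RpS13 (61.4). The 5 with no candidate, named in the same way, were RpL38, RpL10Aa, RpS10a, RpS19b and RpS5b; RpS5b and RpS19b are gene copies known from the germline.

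The other 22 lists did not pass the adjusted threshold, and none of them had an unadjusted p under 0.05 either. Promoter peaks were often shared, and 4250 of the 7757 genes remained when genes sharing a peak were left out, a setting chosen after the data were seen. Mitochondrial ribosomal protein genes had 23 of 65 (35.4%, odds ratio 1.01, 0.576 to 1.72). Without shared peaks they had 1 of 12 (0.244, 0.00566 to 1.68), and with the nearest gene within 5 kb 8 of 48 (0.439, 0.177 to 0.952, adjusted exact p = 0.12), neither past the threshold. Of these genes mRpS10, mRpS23 and mRpL41 held peaks of signal 1110, 1059 and 1034, the first and second of them shared with Art3 and CenG1A, and mRpL23 held 595. Proteasome subunit genes had 7 of 27, among them Rpn5 (287), Rpn3 (224), Rpn6 (179) and Rpn2 (140), and their odds ratio turned from 0.642 to 1.07 without replicate 1. Cell cycle genes had 12 of 22 (odds ratio 2.21, 0.874 to 5.72), led by Dp (348), dup (234), aurA (174) and polo (112). Heat shock genes had 5 of 10, with 529 at Hsp83, 384 at Hsp27, 284 at Hsp26 and 116 at DnaJ-1; this list passed without replicate 1 (odds ratio 7.69, adjusted exact p = 0.047) and not without replicate 2 (1.27, adjusted exact p = 0.85). Polycomb and Trithorax group genes had 8 of 18, with Trl (219), brm (212) and E(z) (137) after ph-p.

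Among lists tied to the nervous system, axon guidance and adhesion genes had 13 of 25 (odds ratio 1.99, 0.838 to 4.79, adjusted exact p = 0.37), led by unc-5 (250), Lar (181), Sema1a (136) and Fas2 (128). Proneural and neuroblast factors had 8 of 23, with brat at 169, emc at 140, da at 111 and Dr at 103. Notch pathway genes had 10 of 20, with gro, a corepressor that HES proteins recruit, at 499, aph-1 at 285, numb at 233 and aPKC at 149. Glial genes had 4 of 8 (moody 569, pnt 123, Nrg 96.6, loco 85.8), and genes of differentiated neurons 2 of 11 (elav 449, Csp 88.7). The peaks at Nrg and loco ranked below 4097 in replicate 1, and the peak at Csp did so in replicate 2. Without replicate 2 the odds ratio of glial genes turned from 1.84 to 0.709 and that of Notch pathway genes was 1.18 in place of 1.84, and without replicate 1 that of differentiated neurons was 0.240 in place of 0.408. With each peak assigned to its nearest gene within 5 kb, axon guidance genes passed (odds ratio 3.32, adjusted exact p = 0.029), as did dorsoventral patterning genes (3.87, adjusted exact p = 0.023).

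Patterning and tissue lists also spread around the share of all genes. Segmentation genes had 5 of 18 (bcd 153, nkd 113, ci 88.7, ptc 84.8), dorsoventral patterning genes 8 of 19 (cact 404, tup 137, rho 127, brk 121), germline genes 3 of 9 (bgcn 276, nanos 141, tud 105), and genes of trachea and epidermis 5 of 10 (shot 224, Ubi-p63E 151, bnl 134, crb 91.5). Ubi-p63E, listed there as Ubiquitin-63E, is a ubiquitin gene and does not stand for these tissues. Genes of gut, fat body and hemocytes had 3 of 9 (fkh 467, ush 105, cad 82.2), and muscle genes 2 of 16 (mbc 276, sls 121; odds ratio 0.262, 0.0289 to 1.14). The mbc peak is shared with Nup98-96, a nuclear pore gene. Without genes that share a peak muscle genes had 1 of 14, and with the nearest gene within 5 kb the odds ratio was 1.29 (0.428 to 3.55). Without replicate 1 the odds ratio of muscle genes was 0.523 and that of germline genes 0.548 in place of 0.919. Without replicate 2 that of germline genes turned to 1.42 and that of trachea and epidermis from 1.84 to 0.591, while gut, fat body and hemocytes had 0.354 in place of 0.919 and segmentation genes 0.443 in place of 0.706. Of the peaks named for these lists, those at ci, crb and cad ranked below 4097 in replicate 1 and that at ptc in replicate 2, and no replicate 2 candidate overlapped the peak at tud. The 8 Hox genes all had a candidate and none a thresholded peak (odds ratio 0, upper bound 1.08, adjusted exact p = 0.37), with lab at 50.4 and pb at 38.8. Lists chosen as silent in most embryonic cells rarely had any candidate: 6 of 176 chemosensory receptor genes, 1 of them with a thresholded peak (Ir60e, 117; odds ratio 0.367, and 0.192 and 0.161 without replicates 1 and 2), 3 of 23 testis-specific genes (Mst87F at 24.9 and mia at 54.7) and 2 of 27 genes of adult and larval products (Rh4 at 22.5 and Sgs3 at 21.9). Against all protein-coding genes in place of genes with a candidate, chemosensory receptor genes (odds ratio 0.0231, adjusted exact p = 1.2e-14) and adult and larval products (0) passed as less often bound. With that background Notch pathway genes (3.16) and cell cycle genes (4.94) passed as more often bound.

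**Figure D3:**
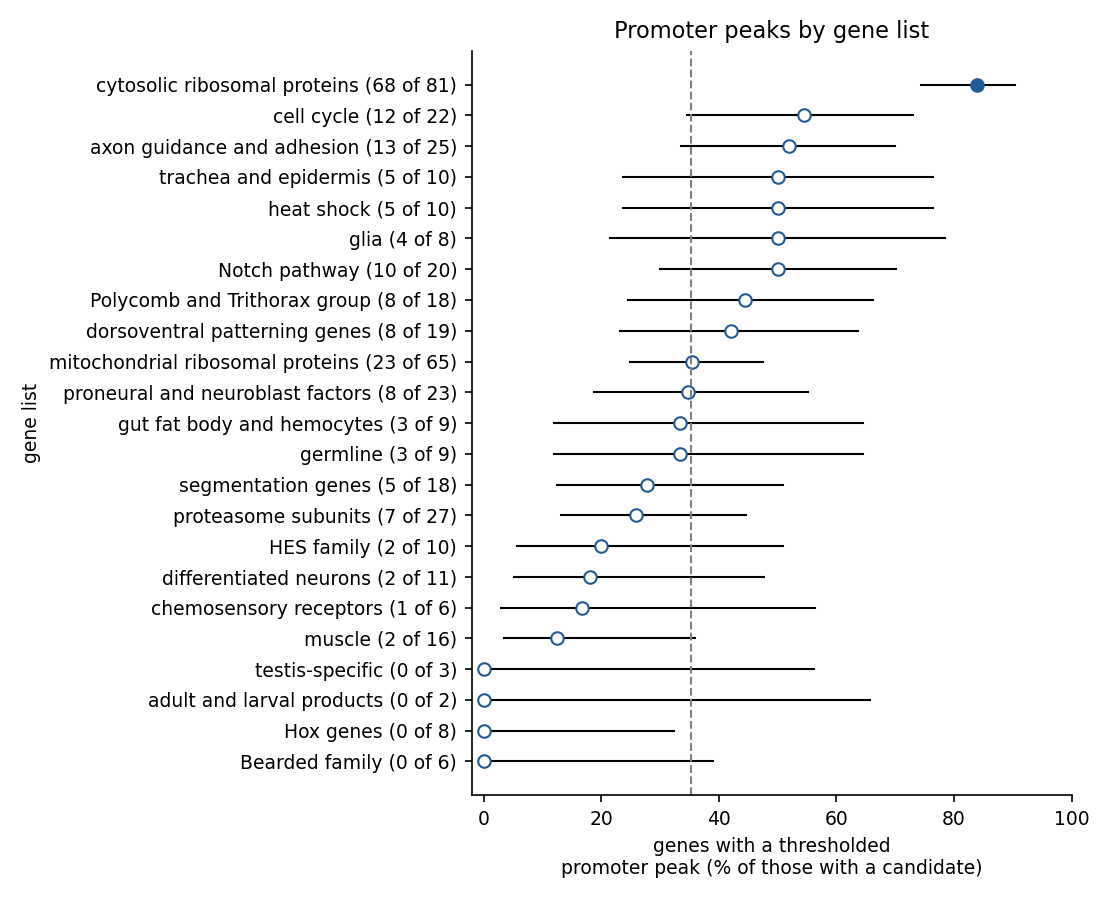
Share of genes with a thresholded promoter peak among genes of each list with a candidate (x axis, %), with 95% Wilson intervals as lines; filled points passed the adjusted threshold and the dashed line marks the share over all genes, 35.2%. Cytosolic ribosomal proteins (68 of 81) lie to the right of every other list.

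The HES family, basic helix-loop-helix-Orange repressors that include Sidpn, had thresholded promoter peaks at 2 of 10 members with a candidate (odds ratio 0.459, 0.0474 to 2.30, adjusted exact p = 0.80), and at 1 of 10 without replicate 2 (0.197). These were E(spl)m7-HLH (signal 170) and E(spl)m3-HLH (137); the latter ranked 554 in replicate 2 and 9521 in replicate 1. Candidates below the threshold lay at hry (52.3), E(spl)mgamma-HLH (40.5), dpn (39.6), E(spl)mbeta-HLH (39.3), Sidpn (38.9), E(spl)m8-HLH (34.8), cwo (24.6) and E(spl)mdelta-HLH (24.2), while E(spl)m5-HLH, Hey and Hesr had none. Of the Bearded family, small proteins encoded beside several HES genes, 0 of 6 members had a thresholded peak, with E(spl)malpha-BFM at 79.1 and E(spl)m2-BFM at 50.9.

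At the genes the labels can mean, the best rank of any peak was 2102. The gene side (FBgn0016061, 3R, 27375088 to 27437482), which encodes a cell surface protein that guides motor axons, had 2 thresholded peaks in and within 5 kb of it, where 2.22 would lie at uniform density. One was in an intron (27407009 to 27407418, rank 2102) and the other at the promoter of the neighbouring CG44290 (27440622 to 27441031, rank 2410), also named after its peak was seen. The pooled list held 7 candidates there, where 16.2 would lie, replicate 1 held 11 and replicate 2 held 7, and the candidate at the promoter of side itself ranked 9753. Sidpn (FBgn0032741, 2L, 19027710 to 19030780) had 0 thresholded peaks within 5 kb, where 0.4 would lie, and 8 pooled candidates, where 2.93 would lie. Replicate 1 held 5 and replicate 2 held 9, and the 8 included 2 pairs of overlapping peaks. The strongest pooled candidate, 840 bp from the start site of Sidpn, had a signal of 65.6 and rank 5694. Several of the 8 pooled candidates lay at promoters of the neighbouring genes mib2, hook and CR43700, named after their peaks were seen. Within 20 kb of Sidpn lay 3 thresholded peaks. Without replicate 2 there was 1 within 5 kb, ranked 4026 in replicate 1. It overlapped a pooled candidate with its summit 17 bp from the start site of mib2.

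Genes of small nuclear RNAs lay near thresholded summits more often than near other candidates, on small counts. Summits within 500 bp of such a gene numbered 8 of 4097 thresholded peaks and 10 of 24883 others (odds ratio 4.87, 1.67 to 13.7, Fisher's exact test, adjusted p = 0.0074). Named after the count was seen, they lay at the 7SKa gene, at U1 genes at 82Eb and 95Ca, and at genes of U2, U5 and U6. The call was lost without replicate 1 (odds ratio 2.32, adjusted exact p = 0.26) and in the 1000 strongest peaks, where no such summit lay. Genes of tRNAs (16 summits, odds ratio 0.758, 0.420 to 1.28) and snoRNAs (17, odds ratio 1.33, 0.734 to 2.26) did not pass, and rRNA genes had no summit in either set. With a window of 200 bp tRNA genes passed as less frequent (odds ratio 0.275, adjusted exact p = 0.0080), and with 1000 bp snoRNA genes as more frequent (1.65, adjusted exact p = 0.026).

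Chromosome 4, the small and largely heterochromatic autosome, held 14 thresholded peaks, 0.342% of them, against 0.892% of the other candidates (odds ratio 0.381, 0.205 to 0.654, Fisher's exact test, adjusted p = 6.2e-04). Arm 3L held 819 of 4097 against 5484 of 24883 (odds ratio 0.884, 0.813 to 0.960, adjusted exact p = 0.0097), a call lost without replicate 2 (adjusted exact p = 0.12). Arms 2L, 2R, 3R and X did not pass. In the 1000 strongest peaks the calls of chromosome 4 (odds ratio 0.446, adjusted exact p = 0.23) and 3L were both lost and 2L passed as more frequent (1.26, adjusted exact p = 0.030). Without replicate 1, 2R passed too (1.11, adjusted exact p = 0.032).

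Promoter elements were more frequent around thresholded summits and the E-box patterns CANNTG and GCAGSTG less frequent, in sequence that was poorer in GC (39.1% against 44.3% in the other candidates). The DNA replication-related element TATCGATA was found in 4.61% of thresholded peaks and 1.88% of the others (odds ratio 2.52, 2.11 to 3.00, Fisher's exact test, adjusted p = 8.0e-22). GGTCACACT, bound by M1BP, had an odds ratio of 2.31, the core promoter element GGTATTTT 2.02, GTCACAC 1.76, GAGAGAG 1.30 and the pyrimidine initiator YYCTTTY 1.23, while CGATA, the core of BEAF-32 sites, lay in 32.4% against 24.2%. The extended class A E-box GCAGSTG was less frequent (5.15% against 8.65%, odds ratio 0.573, 0.493 to 0.663, adjusted exact p = 1.0e-14), as were GCCAT (0.749), CANNTG (0.836), CACACACA (0.810), the class C site CACGCG (0.831) and the N-box CACNAG (0.905). CACGTG, CAGCTG, YGTGRGAA, CAGGTAR, AGRKGGC, GGTTCGANNCC and the control AGCGCT did not pass. In all, 14 of 21 motifs passed, 8 as more and 6 as less frequent, and 1 of the 8 was GTGCAC (1.34), included as a control. In the 1000 strongest peaks the calls of GGTCACACT (1.02), GTCACAC (1.18), GAGAGAG (1.09), CACNAG and CACACACA ended, and the control AGCGCT passed as less frequent (0.618). Without either replicate the calls of CACGCG and CACACACA ended, without replicate 1 also that of CACNAG, and within 50 bp those of GTGCAC, CACGCG and CACNAG, while CAGGTAR passed as less frequent within 50 bp and without replicate 2.

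Most of these calls ended when candidates were matched on GC content and promoter status. TATCGATA then had an odds ratio of 1.21 (0.966 to 1.51, adjusted exact p = 0.25), GGTCACACT 1.11 (adjusted p = 0.63) and GCAGSTG 0.921 (0.756 to 1.12, adjusted p = 0.61), and no motif passed as less frequent. The 5 that passed included the control GTGCAC, which had the highest odds ratio of them (1.53, 1.28 to 1.83, adjusted exact p = 5.3e-05). The others were GAGAGAG (1.38, 1.13 to 1.70, adjusted exact p = 0.011), AGRKGGC (1.28, adjusted p = 0.018), YYCTTTY (1.16, adjusted p = 0.011) and CGATA (1.14, adjusted p = 0.022). Since a control passed above them, passing alone does not tie these elements to the tagged protein. AGRKGGC was not among the earlier calls, with an unmatched odds ratio of 0.920 (adjusted exact p = 0.23). Matched on GC content alone, 11 motifs passed, all as more frequent. Among them were GGTCACACT (1.93), TATCGATA (1.77), CAGCTG (1.20, adjusted exact p = 0.027), CACGCG (1.28, adjusted exact p = 0.048) and CACNAG (1.17, adjusted exact p = 0.0090), while YYCTTTY was not (1.06).

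**Figure D4:**
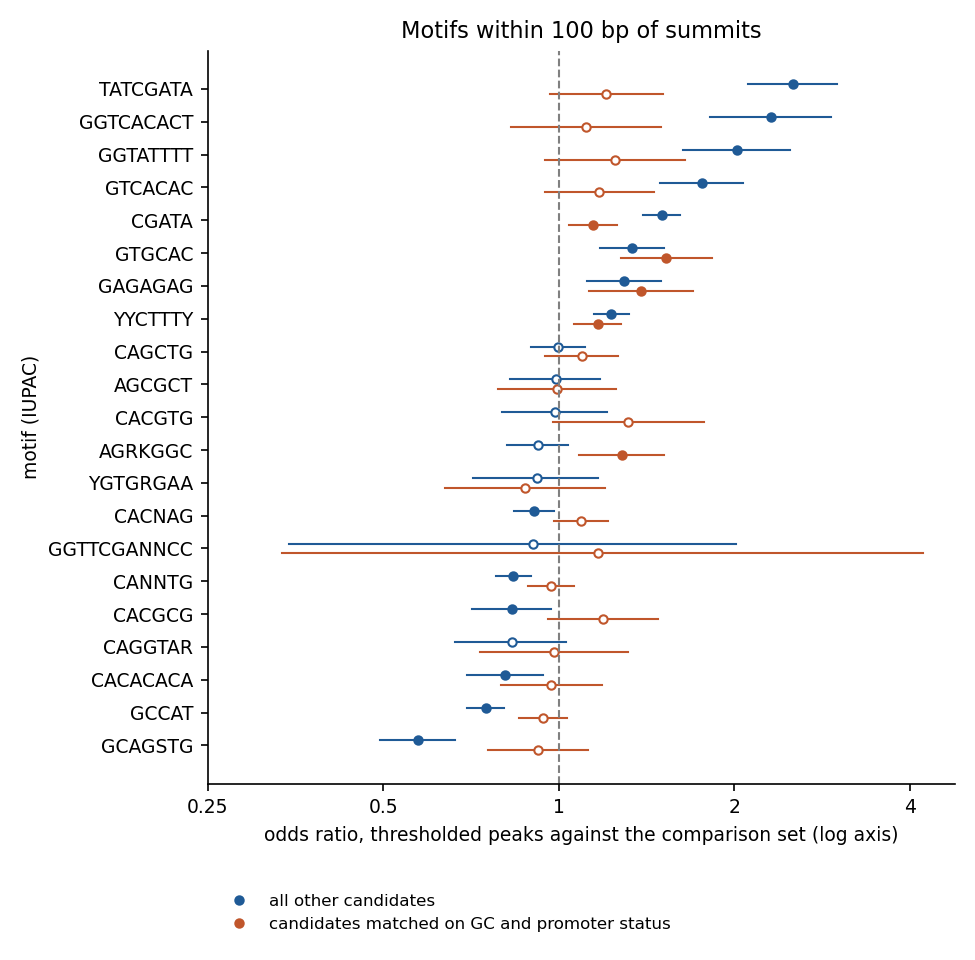
Odds ratio of each motif within 100 bp of summits (x axis, log scale), thresholded peaks against all other candidates or against candidates matched on GC content and promoter status. Lines are 95% intervals and filled points passed the adjusted threshold. TATCGATA moved from 2.52 to 1.21 with matching, and the control GTGCAC from 1.34 to 1.53.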

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

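The extra gene lists behind the comparison of ribosomal protein promoters were added after that result was seen, and both tests of the hexamer were chosen after it was noticed. Apart from the TCT initiator at ribosomal protein promoters, no biological explanation was tested for any pattern, since the design has 1 group. Peaks on sequences outside the 6 major arms entered only the counts, widths, signals, replicate overlap and correlation on dm3. Of the 30000 pooled candidates on dm3, 26 lay there, above the limit of 3 that a count of 0 allows. Among these, 2 on the unplaced sequence U were past the authors' threshold. Nothing sets 0 as the count for such sequences on dm3, so the number is given as a value only.

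Promoters of cytosolic ribosomal proteins held thresholded peaks at an odds ratio of 9.83 (5.37 to 19.4). OXPHOS subunit genes, a list of housekeeping genes, did not show this. Their odds ratio of 0.708 (0.379 to 1.27) lay below the whole interval of the ribosomal list. They do not stand for housekeeping genes in general. Base composition is argued against by near-equal GC content, 43.0 ± 5.25% (SD) at ribosomal promoters and 42.7 ± 7.46% at the others, which left stratifying over GC bins little to move (9.48, 5.20 to 17.3). A list of abundant transcripts without ribosomal proteins did show it, at 4.63 (2.14 to 10.8), so unspecific signal at the most transcribed genes may account for the pattern and stays open. The TCT initiator was matched at 51.9% of the ribosomal genes, of which 85.7% with it and 82.1% without it had a thresholded peak. Of other genes without it, 34.6% had one. These values argue against the matched initiator as the whole source, for the 39 ribosomal genes without a match. A part for it stays open: other genes carrying it had an odds ratio of 1.71 (0.996 to 2.93).

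The extended class A E-box GCAGSTG was rarer in thresholded peaks than in other candidates, with an odds ratio of 0.573 (0.493 to 0.663). After matching on GC content and promoter status it was 0.921 (0.756 to 1.12), so the lower GC content and the higher promoter share of thresholded peaks may account for most of it. Matching left fewer candidates and widened the interval, but the call ended because the odds ratio itself moved towards 1.

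The hexamer ACAGTG, noticed when all arms were searched for frequent words, several of which ranked higher, lay within 100 bp of 18.9% of thresholded summits and 10.9% of the others (odds ratio 1.90, 1.74 to 2.08). On arms 3L, 3R and 4, matched on GC content and promoter status, the odds ratio was 1.73 (1.42 to 2.12), which argues against those properties as the whole source. Of the 179 other arrangements of its letters 0 had an odds ratio as high, which follows in part from how the hexamer was picked. Their median was 0.945 (middle 95% 0.652 to 1.39). They were counted in the same sets matched on GC content, so their values cannot tell whether base composition raised the hexamer. These arms had been part of the search, so the values are not independent evidence, and a sequence preference of the tagged protein or of a factor bound beside it may be a hypothesis but was not tested.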

How the results depend on the processing

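The pairing by mutual best peaks, the removal of genes that share a promoter peak and the removal of near-duplicate summits were chosen after the data were seen; all other settings were planned. Replicate overlap stayed above that of randomly shifted peaks in all 5 alternatives (62.2% to 75.7%). The promoter share stayed past its threshold in all 5 of its own (44.3% to 65.8%), and ribosomal protein genes passed in all 8 alternatives (odds ratios 7.96 to 22.4). At or above their median signal were 2049 thresholded peaks. The correlation moved to 0.64 with 50% reciprocal overlap, 0.46 in pairs at thresholded peaks and 0.70 with mutual best pairs. The classes of small RNA genes past the threshold numbered 2 with windows of 200 or 1000 bp, 0 in the 1000 strongest peaks and 0 to 1 without a replicate; in the 1000 strongest peaks the odds ratio of snRNA genes was 0. Gene lists past the threshold numbered 5 against all protein-coding genes (with Notch pathway genes at 3.16, cell cycle genes at 4.94, chemosensory receptors at 0.0231 and adult and larval products at 0), 3 with the nearest gene within 5 kb (with axon guidance genes at 3.32 and dorsoventral genes at 3.87) and 1 to 2 without a replicate, where heat shock genes ranged from 1.27 to 7.69. In the 1000 strongest peaks, axon guidance genes (0.442) and dorsoventral genes (0.544) turned below 1, neither having passed. Motifs past the threshold numbered 5 with GC and promoter matching and 11 to 13 without a replicate. CACGCG turned to 1.28 and CACNAG to 1.17 with GC matching, to 1.19 and 1.09 with both properties matched, and CACGCG ranged from 0.924 to 1.01 without a replicate; GTGCAC fell to 1.00 within 50 bp. The promoter signal difference was -0.039 with a 200 bp window, 0.083 with 1000 bp and 0.036 to 0.059 without a replicate. Sidpn had 3 thresholded peaks within 20 kb and 0 to 1 within 5 kb without a replicate, the latter overlapping a candidate at the neighbouring mib2. Arms past the threshold numbered 1 in the 1000 strongest peaks, which was 2L and neither of chromosome 4 and 3L, and 1 to 3 without a replicate. Matching equalised GC content and promoter share but also left fewer candidates. For these changes the cause was not tested. Of 30 results for annotation classes 28 kept their direction and side of the threshold. The exceptions were 5' UTRs in the 1000 strongest peaks (0.538, lost) and exons of noncoding RNAs without replicate 1 (0.552, passed). Results for motifs that had passed kept both in 68 of 98 cases, with 24 lost and 6 turned. For arms 5 of 8 did, with 3 lost, and for gene lists 55 of 64, with 7 gained and 2 turned. Of 51 alternatives to the main comparisons 33 stayed the same by the rule used for each, 16 moved, 1 weakened and 1 turned. Of 155 replicate ranks of thresholded peaks at named genes, 8 lay below 4097. The peak at tud had no rank in replicate 2. Depth is unknown, so its limits could not be stated.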

Other observations

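All tests in this part used gene lists chosen after the results above were seen. Of 12 such lists, 3 passed the adjusted threshold over those 12. Genes of abundant transcripts without ribosomal proteins had thresholded promoter peaks at 25 of the 35 with a candidate (71.4%, odds ratio 4.63, Fisher's exact test, adjusted p = 2.2e-04), with signals of 529 at Hsp83, 513 at the promoter shared by the ferritin genes Fer1HCH and Fer2LCH, and 463 at eEF1gamma. Cuticle protein genes had 0 of 16 (upper bound of the odds ratio 0.475, adjusted exact p = 0.0070), and cytochrome P450 genes 3 of 26 (odds ratio 0.239, 0.0459 to 0.792, adjusted p = 0.048), which were Cyp6u1, Cyp317a1 and Cyp6a20.

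The other 9 lists did not pass. Translation initiation and elongation factors had 20 of 40 (odds ratio 1.84, 0.939 to 3.62), with eIF6 at 675 and eIF1 at 348. OXPHOS subunits had 17 of 61, led by ND-ASHI at 254. Aminoacyl-tRNA synthetases had 11 of 28, V-ATPase subunits 11 of 25, mediator and general transcription factors 20 of 56, serpins and serine proteases 6 of 18, nuclear pore genes 4 of 19, small nuclear ribonucleoproteins 4 of 24 and CCT chaperonin subunits 1 of 7. The highest nuclear pore signal, 722 at Nup37, belonged to the peak that also lies at RpS27.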
